A study of Drosophila melanogaster with 6 samples.

How the data were processed

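Total RNA was measured in 3 wild-type and 3 CrebA null mutant samples of Drosophila melanogaster embryos, all sorted on a COPAS biosorter, an instrument that sorts whole embryos. The sample titles name sorting only for the mutants. Per the labels' protocols, RNA was isolated with TriZol and Qiagen RNeasy, then amplified and labelled with an Affymetrix 3' IVT Express kit. The deposited values are RMA expression values on a log2 scale. Per the submitters' processing notes, RMA and Partek were used, with no version or order. The log base is not given in the sources used here and was inferred from the range of the values, from 2.81 to 14.53. Which step each program did, and any filter, is not given in the sources used here. All 6 sample columns of the table were used, and no genome build is given there, so no coordinates are printed.

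Probe sets were named from the platform annotation. Of 18769 probe sets other than 183 Affymetrix controls, 13647 had 1 gene symbol, 402 had several and 4720 had none. Symbols were looked up by gene ID in the RefSeq gene table of assembly Release 6 for 13544 probe sets, and 0 changed. A gene was represented by its single-gene probe set with the highest mean over the 6 arrays, which gave 11982 genes, 1094 of them with over 1 probe set. No probe set was named CrebA, so the planned comparison of CrebA levels was not made.

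Genotypes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, on the deposited values, without further normalization or filter. The test was two-sided with Benjamini-Hochberg adjustment over 18769 probe sets, and a change was called at an adjusted p under 0.05. Gene lists were tested with camera (preset correlation 0.01) on 1 probe set per gene, adjusted over 33 lists, and the union of the 9 early secretory lists was tested on its own. Camera was also run with an estimated correlation and on ranks, and fry as a test of each list alone. The lists held 486 symbols, of which 466 matched by symbol, 11 by synonym and 9 not at all, plus 4 lists taken by symbol pattern, and only hkb was in more than 1 list. The lists, the limma and camera tests and the rule for named genes were fixed before the data were examined, and tests chosen later are named as such where they are given.

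The named genes were CrebA and, among genes called with no overlap between genotypes, the 12 with a symbol other than a bare CG or CR number that fell most and the 12 that rose most. Each list gave up to 4 called members with the largest change and any called member that moved against the majority of called members, or its 2 members with the highest mean where none was called. A bare CG or CR number was to be named only if it had the largest fall or rise of all. None did, though some changed by more than other named genes. Probe sets that list several genes were not named. After the values were seen, levels of named genes and called probe sets were set against 17 Tag control probe sets, whose sequences are foreign to the fly. Where every array of a genotype lay at or below its highest Tag control, the fold was taken against the mean of those highest controls and given as a lower bound.

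The titles give the same replicate numbers in both genotypes, and no label says that a number marks a shared collection. Deviations from the genotype means correlated over probe sets between arrays of the same number, with r of 0.639, 0.852 and 0.563 for replicates 1, 2 and 3. All were over 0.1, the bar used for treating the numbers as pairs. Crossed pairs 1 and 3 also correlated, with r of 0.566 and 0.371. Deviations within a genotype cancel out and replicate 2 stood apart in both, so arrays 1 and 3 correlate under either pairing. The correlations therefore do not settle how replicates 1 and 3 pair. Fits with the replicate number as a block were run beside the main ones and not in their place.

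The scripts were tested on simulated arrays with the means, replicate effects and noise of this comparison, with 200 of 18769 probe sets changed. Without the block 2 of 67 changes of 1.5-fold, 32 of 67 of 2-fold and 55 of 66 of 4-fold were recovered, with 0 unchanged probe sets called. With the block 36, 64 and 64 were recovered, with 8 unchanged ones called. The simulated arrays of the same number shared 1 replicate effect in both genotypes, and the noise came from the blocked fit. The gain with the block was therefore built in, and it does not test whether the numbers mark pairs. Of 33 random lists of 12 genes, the 6 shifted by -0.5 (log2) were called by camera and no other was. Replicate effects were shuffled over probe sets and noise was drawn for each probe set alone. The lists therefore do not test the preset correlation where genes of a list vary together. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.

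Alternatives were filters on dim probe sets, other scalings, variance models, array weights, the replicate block, leaving out each array, other thresholds, other choices of probe set and other set tests. The unmoderated linear model and the robust prior do not enter camera and were run for counts only. Leaving out both replicate 2 arrays, and the block with an estimated correlation, were added after seeing the data.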

Results

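RNA from sorted Drosophila melanogaster embryos was hybridised to 6 Affymetrix Drosophila Genome 2.0 arrays, 3 from wild-type embryos and 3 from embryos null for CrebA, a bZIP transcription factor. Embryos were collected over 8 h and aged for a further 11 h, and the labels place them from stage 11 to stage 15 in one field and to stage 17 in another. Each array gave log2 values for 18952 probe sets, with array means of 6.39 on every array and medians between 5.47 and 5.58. The number of arrays limits the precision. Nothing in the labels says that the replicates came from separate collections, so p-values measure only the spread between these samples, which may be technical.

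The replicate 2 arrays of both genotypes stood apart from the other 4. The first principal component held 53.5% of the variance and placed wild type 2 at 53.5 and mutant 2 at 20.1, against -36.8 to -3.20 for the others. The second component held 32.9% and separated the genotypes, with wild-type scores of -32.0 to -3.15 and mutant scores of 13.6 to 33.8. Wild type 1 and 3 differed with an SD of 0.251 (log2, over probe sets) and mutant 1 and 3 with an SD of 0.226. Pairs within a genotype that included replicate 2 differed with SDs of 0.390 to 0.524.

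**Figure D1:**
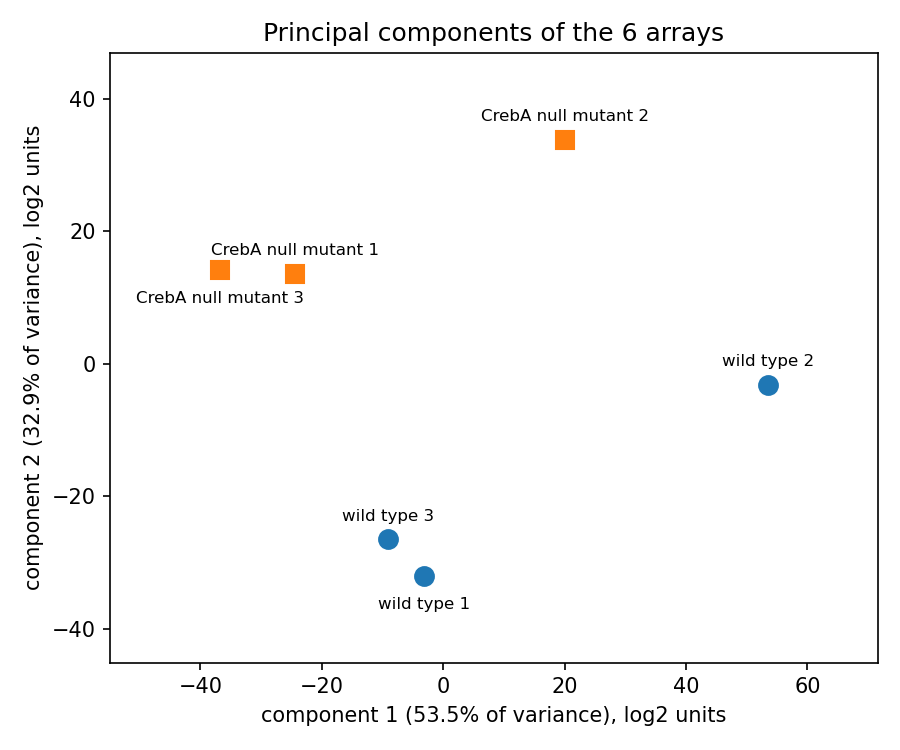
Scores of the 6 arrays on the first 2 principal components of the log2 values (circles, wild type; squares, CrebA null mutant; axes in log2 units). Component 1 (53.5% of the variance) holds the replicate 2 arrays at its upper end, and component 2 (32.9%) separates the genotypes.

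The comparison of CrebA null mutants with wild type asks which transcripts depend on CrebA, and the series title names secretory pathway genes. Genes of the early secretory pathway were lower in the mutants as a group, from the signal recognition particle and the translocon to the COPI and COPII coats. With an estimated correlation the adjusted p of each of these lists was 0.346, and the union of the 9 lists, tested alone, had a p of 0.0460. Single genes changed by far more in both directions. The gene mex1, named for its midgut expression, fell 14.3-fold, from 11.42 ± 0.31 to 7.58 ± 0.33 (log2, SD, n = 3 per genotype), and the serpin Spn28Da rose at least 56.2-fold, to 10.84 ± 0.56 from a level (4.34 ± 0.17) within that of control probe sets foreign to the fly. No probe set was named CrebA in the annotation used here, so the level of the mutated gene was not analysed here and the genotype labels had no check of their own.

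Of 18769 probe sets tested with limma, 267 rose and 171 fell in the mutants at an adjusted p under 0.05. At gene level, with 1 probe set for each of 11982 genes, 228 genes rose and 122 fell, of which 214 and 116 changed by at least 1.5-fold. All 438 called probe sets had mutant values that did not overlap the wild-type values, as did 3554 of all probe sets (18.9%, against 10% by chance for 3 against 3). With the replicate number as a block, 1788 probe sets rose and 1342 fell, and these calls took in all 438. At gene level the block gave 1504 risen and 1103 fallen genes. Scaling each array on ribosomal, proteasome and respiratory chain genes gave 125 risen and 208 fallen probe sets, so that risen ones made up 37.5% of calls rather than 61.0%. This scaling used each array's median level over these genes. It moved the median log2 change of all genes from -0.021 to -0.090, although the median change of these genes themselves was -0.0018. The shift in calls therefore does not by itself show that these genes changed. Their pooled median covers respiratory chain genes with a median change of 0.12 and proteasome genes with one of -0.06, so it does not show that none did. Leaving out 1 array lowered the calls to between 23 risen and 17 fallen (without wild type replicate 1) and 159 risen and 121 fallen (without wild type replicate 2).

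The ranking by size of change leaves out genes named only by a CG or CR number, some of which changed by more. Among the genes that fell most, TRAM, a membrane protein next to the translocon of the endoplasmic reticulum (ER), had a log2 change of -2.38 (SE 0.30, adjusted p 0.0214). Ugalt, a Golgi transporter of UDP-galactose, had a change of -1.82 (SE 0.22), and ImpL1, an ecdysone-inducible gene, fell from 13.46 ± 0.20 to 11.41 ± 0.26 (SD, n = 3). The stress-induced DNase gene Sid fell 5.21-fold, the chitin-binding obstructor gene obst-H 4.93-fold, the Jonah protease gene Jon44E 4.65-fold and the cuticle protein gene Cpr47Eg 4.43-fold. Falls of 3.70-fold for TotE (a Turandot stress gene), 3.45-fold for GluRIID (a glutamate receptor subunit), 3.28-fold for MFS15 (a transporter) and 3.02-fold for path (an amino acid transporter) completed the 12. These 12 had adjusted p-values of 0.00377 to 0.0370.

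Bare CG or CR numbers are left out of the risen genes too. Among the genes that rose most besides Spn28Da, the neuropeptide gene CCHa2 rose at least 9.43-fold, to 8.26 ± 0.21 (SD, n = 3) from 4.71 ± 0.32, and the cuticle protein gene Cpr47Eb 10.7-fold. SNCF rose 8.07-fold, the alpha integrin gene scb 6.81-fold, the antifungal peptide gene Drs 6.69-fold and the methionine sulfoxide reductase gene MsrA 5.41-fold. The mucin gene Muc18B rose 4.18-fold, the phosphate transporter gene NaPi-III 3.59-fold, Bbd at least 2.11-fold, the zinc transporter gene ZnT35C 3.37-fold and the glutathione S-transferase gene GstE1 3.29-fold. On every wild-type array Spn28Da, CCHa2 and Bbd lay at or below the highest of 17 foreign control probe sets (4.81 to 5.28), so each fold is a bound taken against that highest control. SNCF lay there on 2 wild-type arrays and Muc18B on 1, so the order of these genes by fold is uncertain. Of the 438 called probe sets, 39 risen ones lay within these controls on every wild-type array and 13 fallen ones on every mutant array. Adjusted p-values of the 12 risen genes ran from 0.00263 to 0.0406.

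**Figure D2:**
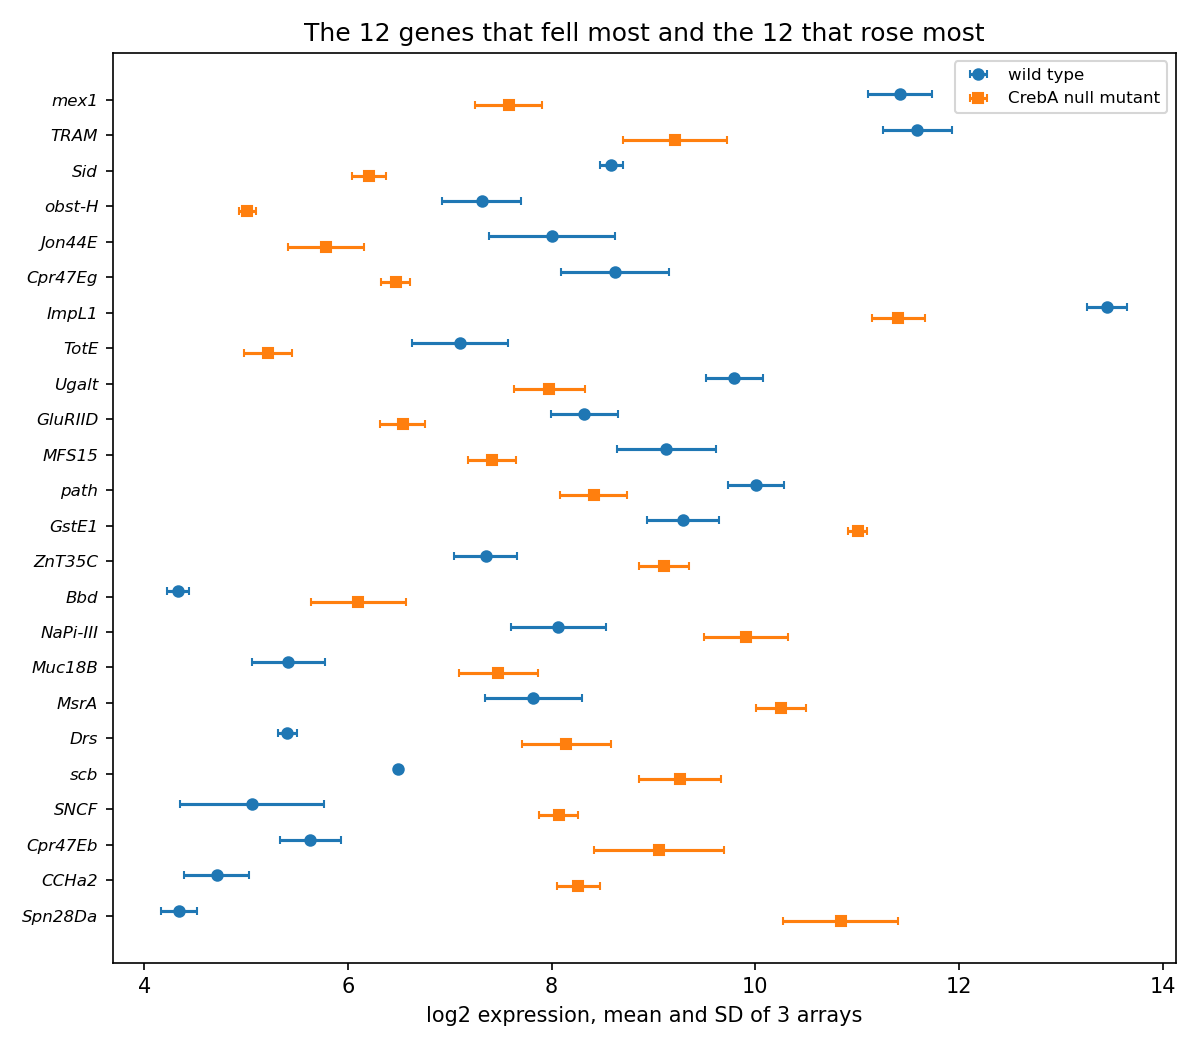
Log2 expression (mean, with bars for the SD of 3 arrays) of the 12 genes that fell most and the 12 that rose most (circles, wild type; squares, CrebA null mutant). Genes named only by a CG or CR number are left out. Spn28Da lies at 4.34 in wild type and 10.84 in the mutants, and mex1 at 11.42 and 7.58.

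Of the measured genes in the 9 lists that make up the early secretory pathway, 20 fell, 0 rose and 84 were not called. Adjusted over the list alone, 55 fell and 1 rose, and with the replicate block 71 fell and 1, the SNARE gene Ykt6, rose. The median log2 change was -0.54, and 91 changes were negative and 13 positive. Fallen genes made up 19.2% of the list and 0.859% of the other genes (Fisher's exact test, two-sided, odds ratio 27.4, 95% confidence interval 15.4 to 47.2, p 1.8e-20). Fisher's test treats genes as independent, while the estimated correlation within this list was 0.225. Its p is therefore too small and its interval too narrow. The list was lower than other genes by camera with a preset correlation of 0.01 (p 8.5e-23) and with an estimated correlation (p 0.0460, and 0.00905 with the replicate block). Without 1 array the count of fallen members ranged from 0 (without CrebA null mutant replicate 1) to 13 (without CrebA null mutant replicate 2).

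Signal recognition and entry into the ER came first along the pathway. In the list of the signal recognition particle and its receptor, 2 of 7 measured genes fell, 7 adjusted over the list alone and 7 with the replicate block (median log2 change -0.91, camera adjusted p 2.9e-07, adjusted p 0.346 with an estimated correlation). The particle subunits Srp68 and Srp72 had changes of -1.03 (SE 0.17) and -0.86 (SE 0.08). In the list of the translocon and signal peptidase, 7 of 11 fell, 10 adjusted over the list alone and 11 with the block (median -1.06, adjusted p 1.1e-11, adjusted p 0.346 with an estimated correlation). Besides TRAM, the signal peptidase genes Spase12, twr and Spase25 changed by -1.35 (SE 0.20), -1.20 (SE 0.17) and -1.13 (SE 0.12).

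Of the ER chaperone and disulfide formation genes, 1 of 12 fell, 5 adjusted over the list alone and 9 with the block (median -0.39, camera adjusted p 7.4e-05). Manf, an ER-resident factor, had a change of -0.95 (SE 0.15). Of the N-glycosylation genes, 1 of 19 fell, 3 adjusted over the list alone and 7 with the block (median -0.24, adjusted p 0.00131). That gene was Stt3B, which encodes a catalytic subunit of the oligosaccharyltransferase (-0.78, SE 0.11). With an estimated correlation the adjusted p was 0.346 for the chaperones and 0.366 for N-glycosylation.

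Vesicle coats and cargo receptors were lower too. COPII coat genes had 1 of 7 fallen, 4 adjusted over the list alone and 6 with the block (median -0.63, camera adjusted p 4.7e-04), with Sec31 at -0.86 (SE 0.15). COPI coat genes had 2 of 8 fallen, 8 adjusted over the list alone and 8 with the block (median -0.87, adjusted p 5.9e-07), with alphaCOP at -1.08 (SE 0.16) and ArfGAP1 at -0.96 (SE 0.13). In the p24 and cargo receptor list 2 of 9 fell, 7 adjusted over the list alone and 7 with the block (median -0.98, adjusted p 3.7e-06). These were ergic53, with changes of -0.98 and -1.30 in its 2 probe sets, and Surf4 (-0.50, SE 0.08). The adjusted p was 0.346 for each of these 3 lists with an estimated correlation.

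Of the Golgi tether and matrix genes 3 of 20 fell, 7 adjusted over the list alone and 11 with the block (median -0.34, camera adjusted p 7.5e-04, adjusted p 0.346 with an estimated correlation). GM130 and Grasp65, which build the cis-Golgi matrix, changed by -1.26 (SE 0.21) and -1.25 (SE 0.15), and the tether subunit gene Cog1 by -0.68 (SE 0.09). Of the ER to Golgi SNARE and Rab genes 1 of 11 fell, the SNARE gene Sec20 (-1.21, SE 0.09). Adjusted over the list alone 2 fell and 1 rose, and with the block 5 fell and 1 rose. This list did not pass the set test (median -0.31, adjusted p 0.0743). The size of the change differed between the 9 lists (permutation test on gene changes with 100000 shuffles, p 1e-05, the smallest they can give), and among the 61 genes with a mean level of at least 9 (p 4e-05), a test chosen after the values were seen, which kept 1 of 20 Golgi tether genes and 3 of 11 SNARE and Rab genes. Both tests treat genes as independent, while the estimated correlation within lists reached 0.894 (COPI coat), so these p-values are too small.

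**Figure D3:**
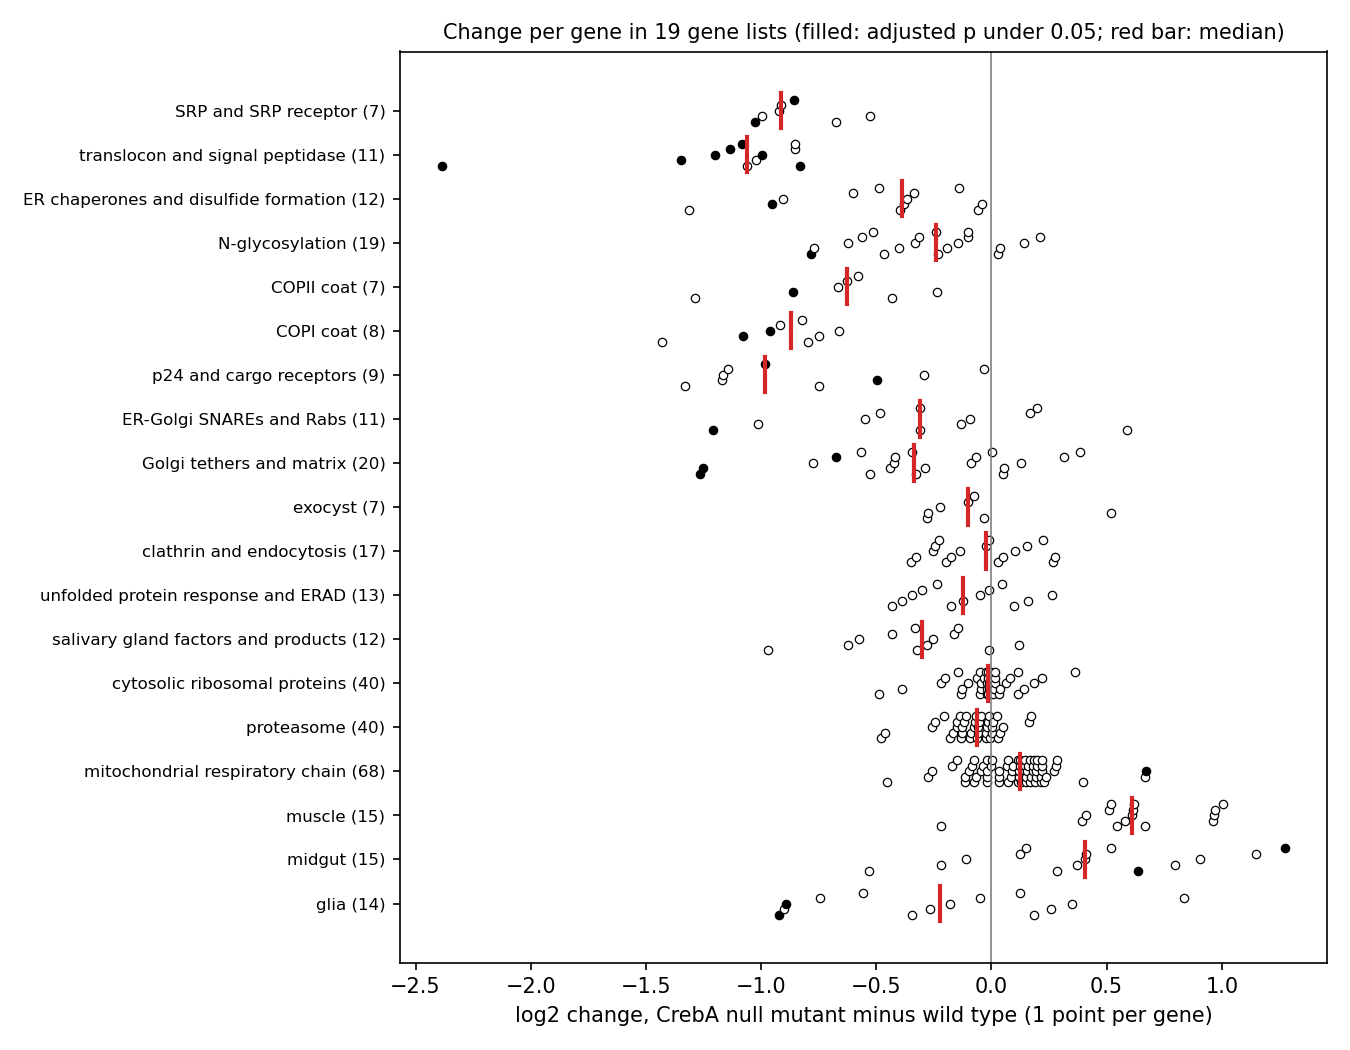
Log2 change (mutant minus wild type, 1 point per measured gene, numbers of genes in brackets) in 19 gene lists, with filled points for an adjusted p under 0.05 and a red bar at each median. Medians of the first 9 lists lie between -1.06 and -0.24, and those of the ribosomal and proteasome genes at -0.01 and -0.06.

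Later steps of traffic did not pass the set test, nor did the ER stress response and degradation. None of 7 exocyst genes (median -0.10, camera adjusted p 0.333), 17 clathrin and endocytosis genes (-0.02, 0.481) or 13 genes of the unfolded protein response and ER-associated degradation (-0.12, 0.165) was called, and none was adjusted over each list alone. With the block 1 exocyst gene rose and 1 fell, and 2 and 3 genes of the other lists fell. The exocyst genes Sec8 and Exo84 had changes of -0.28 (SE 0.16) and -0.28 (SE 0.07), the clathrin chain genes Chc and Clc -0.23 and -0.24, and the degradation and stress genes TER94 and crc -0.05 and -0.30. Housekeeping classes moved little. None of 40 ribosomal protein genes (median -0.01, adjusted p 0.777) or 40 proteasome genes (-0.06, 0.190) was called, adjusted over all genes or over each list alone, and RpLP1 and Rpn6 had changes of 0.02 and -0.07. With the block 2 ribosomal protein genes and 1 proteasome gene fell. Of 68 respiratory chain genes 1 rose in both adjustments, COX7AL2 (at least 1.44-fold, with wild-type levels within those of the foreign controls), and with the block 4 rose and 1 fell. The list was higher as a group (median 0.12, adjusted p 0.0112, adjusted p 0.621 with an estimated correlation).

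Tissue lists moved in both directions. Of 12 salivary gland genes 0 were called, 2 fell adjusted over the list alone and 5 with the block, and the list was lower (median -0.30, camera adjusted p 0.00489, adjusted p 0.346 with an estimated correlation). Its brightest members, ps and Papss, had changes of 0.12 (SE 0.68) and -0.28 (SE 0.13). Of 15 muscle genes 0 were called, over all genes or the list alone, and 11 rose with the block. The list was higher (median 0.61, adjusted p 4.7e-04, adjusted p 0.574 with an estimated correlation), with Mlc1 and Tm2, which encode a myosin light chain and a tropomyosin, at 0.39 (SE 0.12) and 0.55 (SE 0.26). Of 15 midgut genes 2 rose, over all genes and over the list alone, and 5 with the block (median 0.41, adjusted p 5.0e-04, adjusted p 0.346 with an estimated correlation). These were the protease genes alphaTry (1.28, SE 0.16) and Jon25Bi (0.63, SE 0.08), the latter within the levels of the foreign controls on 2 of 3 wild-type arrays. The midgut list was dim, with a median wild-type level of 5.99 against 4.81 to 5.28 for the highest foreign controls. It did not hold mex1 or Jon44E, which fell.

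Of 14 glial genes 2 fell, the sodium pump subunit gene nrv2 (-0.92, SE 0.11) and the glial fate gene gcm (-0.89, SE 0.13), 2 fell and 1 rose adjusted over the list alone, and with the block 5 fell and 1 rose (list adjusted p 0.0999). Of 12 fat body genes 1 fell, over all genes and over the list alone, the lipid transfer gene Mtp (-1.04, SE 0.18, list adjusted p 0.0743), and with the block 3 fell and 1 rose. Of 16 Malpighian tubule and hindgut genes 1 rose in both adjustments, the proton pump subunit gene VhaSFD (0.62, SE 0.10), and 6 rose with the block (list adjusted p 0.0743, and 0.0451 with the block). None of 18 neuronal genes was called in either adjustment, with fne and elav at -0.09 and -0.02, and with the block 6 rose and 1 fell (list adjusted p 0.0726, and 0.00976 with the block). None of 8 tracheal genes was called in either adjustment, with rib and sinu at -0.37 and -0.13, and 3 fell with the block (list adjusted p 0.0743, and 0.0347 with the block). With an estimated correlation the adjusted p under the block was 0.587 for the tubule, neuronal and tracheal lists.

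Of 110 cuticle protein genes 4 rose and 1 fell, 4 rose and 3 fell adjusted over the list alone, and 22 rose and 17 fell with the block (median 0.01, camera adjusted p 0.881). Besides Cpr47Eb and Cpr47Eg, Cpr64Ac and Cpr76Bc rose by log2 changes of 1.55 (SE 0.20) and 1.32 (SE 0.15), the latter from levels within those of the foreign controls on 2 of 3 wild-type arrays. Of 9 immune effector genes 1 rose, Drs, and 3 rose adjusted over the list alone, with 3 risen and 1 fallen with the block (list adjusted p 0.0743, and 0.00815 by fry). Of 20 chitin and cuticle enzyme genes 0 were called, 1 fell adjusted over the list alone, and 7 rose and 1 fell with the block (adjusted p 0.122). The remaining lists had no called gene and did not pass the set test. They were 12 basement membrane genes (adjusted p 0.284), 16 haemocyte genes (0.777), 21 maternal transcripts (0.0834), 20 early patterning genes (0.577), 14 germline genes (0.203), 6 heat shock genes (0.481) and 14 cell cycle genes (0.229). With the block 2, 0, 3, 2, 2, 0 and 0 of these rose and 0, 1, 0, 3, 0, 0 and 2 fell. Adjusted over each list alone, 1 basement membrane gene, 1 maternal transcript and 1 early patterning gene rose, 1 early patterning gene fell, and the others had none.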

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

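Direction held for the early secretory pathway list, whose p stayed under 0.05 in 20 alternatives run with camera and with fry (0.00467), but the counts of calls depended strongly on the variance model and on single arrays. With the replicate block the counts were 1788 risen and 1342 fallen probe sets, 1504 and 1103 genes, and 71 fallen early secretory genes. Array weights gave 1335, 1109, 1137, 848 and 61 in that order. The unmoderated linear model gave 13, 10, 9, 6 and 1. Leaving out 1 array gave 23 to 159 risen and 15 to 121 fallen probe sets, 16 to 136 risen and 11 to 82 fallen genes, and 0 to 13 fallen early secretory genes. Without wild type replicates 1, 2 and 3 there were 23, 159 and 70 risen probe sets, and without mutant replicates 1, 2 and 3 there were 30, 135 and 44. Without replicate 2 of both genotypes, chosen after seeing the data, there were 581 and 424 probe sets, 506 and 325 genes and 47 fallen early secretory genes, and the SNARE and Rab list passed (adjusted p 0.0374). Of the 350 called genes, 320 were among the 831 called there. Scaling on housekeeping lists gave 125 risen probe sets and 103 risen genes, and 160 of the 350 called genes were also called. A fold of at least 2 left 127 and 89 probe sets and 107 and 63 genes. The treat test against 1.2-fold left 93, 63, 78 and 42, and an adjusted p under 0.01 left 33, 23, 26 and 18. An unadjusted p under 0.05 with 1.5-fold gave 721, 507, 616 and 400. Of 12 lists called by camera, 0 were called with the correlation estimated per list, with or without the replicate block. The adjusted p was 0.346 in the plain fit for 7 early secretory lists that had been called and 0.366 for N-glycosylation, and with the block 0.296, or 0.351 for the COPII coat. With fry 4 lists were called, of which 3 were among these 12 (the signal recognition particle, translocon and Golgi tether lists) and 1 was not (the immune effectors, adjusted p 0.00815). Its adjusted p-values were 0.0506 for the ER chaperones, the COPII coat and the COPI coat, 0.149 for N-glycosylation and 0.0753 for the p24 list. Leaving out 1 array kept every called early secretory list past the threshold, and 13 to 16 lists were called, with adjusted p-values of 0.0505 to 0.129 for the SNARE and Rab list. The respiratory chain list lost its call without wild type replicate 1 (adjusted p 0.119), wild type replicate 3 (0.101) or mutant replicate 2 (0.121) and without _s_at and _x_at probe sets (0.147), and the salivary gland list without mutant replicate 2 (0.0816). The cuticle protein list turned lower without wild type replicate 2 (median -0.10, adjusted p 0.0109), and its adjusted p without 1 array reached 0.874. The cause was not tested for any of these changes. Of 49 named genes that were called, 7 to 30 kept their call without 1 array, 49 did with the replicate block, and 0 changed sign in any alternative. Under the unmoderated linear model 3 kept their call, and 35 did when scaled on housekeeping lists. The block changed no call of a list other than those of the neuronal, tracheal and tubule lists. The other settings for the CrebA level were not run, since no probe set was named CrebA. Genes near the lower end of the scale have little signal over background, which limits their fold changes.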

Other observations

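The tests of the salivary gland, of array scaling and of younger embryos, and the gene families and single genes of the next paragraph, were chosen after the results were seen. The other tests below were set before their own values were seen. The stage test among them used an axis built on replicate 2 standing apart, which was itself seen in these data. For the salivary gland the bound was also made stricter after its value was seen, and under the first bound, an interval above 0, the explanation would have been argued against. For RNA quality, in both paragraphs that weigh it, a condition by pair or within genotype was added after the values were seen, and without it this explanation would also have been argued against.

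Gene families were compared by symbol prefix, 77 families with at least 8 measured genes and 154 tests in all. These tests also treat genes as independent, so their p-values may be too small. Of 9 SmydA genes, which encode SET and MYND domain proteins, 4 rose (SmydA-2, SmydA-3, SmydA-5 and SmydA-8, Fisher's exact test, adjusted p 0.00169), with log2 changes of 0.64 to 1.34, the lowest being that of SmydA-5, whose wild-type levels lay within those of the foreign control probe sets. Of 17 genes with the prefix Sec, 4 fell (Sec20, Sec31, Sec61alpha and Sec61beta, adjusted p 0.00169). The neighbouring tetraspanin genes Tsp42Ec, Tsp42El, Tsp42En and Tsp42Eo rose, 4 of 32 Tsp genes, and this family did not pass (adjusted p 0.116), nor did GstE with 3 of 13 risen (adjusted p 0.0867). For 2 genes another probe set changed far more than the one that stands for the gene. A probe set of RFeSP rose at least 21.1-fold, to 9.42 from a level within the foreign controls (4.57, adjusted p 0.00263), while the brighter one had a change of 0.29. A probe set of pip fell by 2.06 (adjusted p 0.0122), while the brightest had a change of -0.33. The fall of pip was not confined to that probe set, as another called one had a change of -1.06.

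For the lower level of the early secretory genes array scaling is argued against, since 148 ribosomal, proteasome and respiratory chain genes had a median change of -0.0018 (95% bootstrap interval -0.018 to 0.027). The list lay 0.336 higher in replicate 2 than in the others, but a shift along this axis, whose slope over other genes predicted a share of 0.0619 of the list's change (0.0412 to 0.0861), is argued against as the whole cause, since it would then have raised cuticle protein genes by 0.823 against an observed -0.0015 in replicates 1 and 3 (-0.0798 to 0.0555, chosen after the values were seen). As a part of the cause it stays open, since muscle genes (0.573, expected 1.54) and neuronal genes (0.313, expected 1.46) moved its way. RNA quality stays open, since 3' to 5' differences overlapped between genotypes for 3 of 3 control genes but were lower in the mutant of every pair for 2, by 0.0720 on average for actin and 0.101 for eIF-4a. Salivary gland markers fell by less than the secretory list (difference of medians 0.236, 0.0241 to 0.449). If the markers were confined to the gland, a loss of gland cells should lower them at least as much as genes that other tissues also express. That was not checked, and hkb is also in the early patterning list. The difference therefore cannot decide on that loss as the whole cause, and it did not pass the stricter bound. A loss of gland cells stays open as the whole or a part of the cause. The markers were lower too, and sage, PH4alphaSG1, sens and eyg fell with the replicate block. Expression levels alone do not test a direct dependence on CrebA.

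The distance of the replicate 2 arrays from the others may reflect younger embryos, and this could not be settled. Cuticle protein genes lay lower in replicate 2 (median -0.480, 95% bootstrap interval -0.698 to -0.224), as did muscle genes (-0.898), neuronal genes (-0.850) and 6 heat shock and stress genes (-1.04). Early patterning genes were also lower (-0.334), which speaks against it, and cell cycle genes lay at 0.0265. RNA quality also stays open, since both replicate 2 arrays lay outside the other 4 in 0 of 3 control genes, but each lay outside its own genotype in 1 of 3. No group of the design separates replicate 2, so no biological explanation other than embryo age was tested.

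Large changes such as those of Spn28Da and mex1 may come from genetic background rather than from CrebA. Genes on arm 3L, which carries CrebA, were called at 1.5-fold or more at an odds ratio of 1.203 against 2L, 2R, X and 4 (Fisher's exact test, 95% confidence interval 0.898 to 1.60, p 0.210), so a wider background of the chromosome cannot be told apart from an effect of genotype. The share called was 3.11% on 3L, above 2.89% on 3R, 2.54% on 2L, 1.71% on X and 1.54% on 4, but below 3.38% on 2R. The odds ratio pooled both directions, and no test was run by direction. On 3L 40 genes rose and 33 fell, of 2344. On 2R 57 rose and 25 fell (of 2427), on 2L 40 and 16 (of 2205) and on X 25 and 7 (of 1873). On 3R these were 52 and 34 (of 2974), and on 4 they were 0 and 1 (of 65). Falls were thus relatively more frequent on 3L than on 2L, 2R or X, and rises were not. A haplotype next to the gene that raised the odds of a call 2-fold is argued against for the set of calls, since 5 of the 200 measured genes nearest to CrebA were called (2.5%, against 3.17% on the rest of the arm, odds ratio 0.783, 0.243 to 1.95). A smaller excess, or a haplotype that also spans the rest of the arm, stays open. Single background differences on other chromosomes stay open, as no second mutant line was used here.

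With 10 splits of the 6 arrays no share under 0.05 can be reached. The real split, 1 of the 10, gave 438 called probe sets, 350 genes and 20 fallen early secretory genes, and the highest of the other splits gave 0 of each. Of the 4 splits that part all 3 pairs, the real one gave 3130 probe sets with the replicate block and each of the other 3 gave 0.

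Of the 183 Affymetrix control probe sets 0 passed an adjusted p under 0.05 by limma, and 5 had an unadjusted p under 0.05. The largest change was 1.25 (SE 0.18, adjusted p 0.0870, from 5.27 to 6.52) in a control probe set that is not one of the fly housekeeping controls. In the main test alphaCOP, with a similar ratio of change to SE (-1.08, SE 0.16), had an adjusted p of 0.0323. The absence of a called control therefore depends on the adjustment. Besides this, 3 GAPDH control probe sets had changes of 0.587 to 0.657 (adjusted p 0.414 to 0.546), which exceed the early secretory list's median in size. The other GAPDH control probe sets did not rise, with changes of -0.383 to -0.009, so the GAPDH controls did not move together.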
